A study of Homo sapiens with 6 samples.

How the data were processed

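RNA from A549 cells, a line from a human lung adenocarcinoma, was sequenced 72 hours after reverse transfection with siRNA at 10 nM. One group received an siRNA pool against RPS19 (siRPS19) and the other a non-targeting control (siOTP), with 3 biological replicates in each group per the labels. The siRPS19 pool and the control belong to different product lines of siRNA (siGENOME and ON-TARGETplus), so reagent chemistry differed along with the target. Total RNA was purified on columns and made into libraries with a standard Illumina TruSeq RNA kit, read as pairs. The labels do not say that the kit marked strand, so reads of overlapping antisense genes cannot be told apart here.

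Per the submitters' processing notes, the tools were TopHat2 (2.0.8b), HTSeq, DESeq and R (3.0.2), and the genome build was hg19. The counting mode and the gene annotation release are not given in the sources used here. The authors deposited read counts per Ensembl gene for each of the 6 libraries, as whole numbers without normalisation. The deposited RPKM table holds 1 value per group and not per library. Tested on the table, each group's RPKM equalled the mean count plus a pseudocount, divided by transcript length and by the group's total, for 100% of 62729 genes in both groups, within a tolerance of 0.0051 RPKM. The mean counts matched those recomputed from the libraries within a relative tolerance of 0.001. The authors' RPKM was used for description and for 1 alternative, and the counts for every test. Gene symbols, coordinates and transcript lengths are those of the authors' table, which lacks 423 of the 63152 genes counted.

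Counts assigned to genes totalled 20814110 to 23889372 per library. Of the 5 entries that name no gene, reads outside genes made up 3.39% to 3.85% of all entries in siOTP and 5.13% to 6.36% in siRPS19, and ambiguous reads 8.10% to 8.24% and 7.50% to 7.60%. These entries were left out of library sizes and tests.

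Genes were kept with filterByExpr in edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17171 genes. Libraries were scaled with TMM factors, and the groups were compared with edgeR's quasi-likelihood test (robust glmQLFit, then glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes below come from this test unless another tool is named. CPM values are TMM-normalised. The standard error of a log2 fold change was derived from the fold change and its F statistic. Because 3 libraries against 3 allow 10 splits, an exact two-sided permutation test of a single value cannot go below 0.1. On counts simulated for siRPS19 against siOTP over 16806 genes, 89.6% of 67 genes changed 1.5-fold were recovered. So were 97.0% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 9 false calls. The simulation gave every gene the same biological spread and changed only these genes, in both directions alike. In the real data 78.3% of tested genes were called, so these rates describe the simulated setting only.

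Before the data were examined, 35 gene lists with 1155 symbols were fixed, of which 1153 matched a gene. Symbols were matched through the files' own names, and current symbols and synonyms from gene name tables. The 33 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01), adjusted over these lists. Camera with an estimated correlation was an alternative. The fry test was also run, but it asks whether a list's genes moved, on balance, one way, and not whether they differed from other genes. Ranges given for lists come from camera alone.

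Named in the text, by a rule also set before the data were examined, are RPS19, genes named whatever their result (among them CDKN1A, MDM2, MYC, RPL5, RPL11 and GDF15), and the 8 largest rises and 8 largest falls. These last had to pass the test, reach a mean of 5 CPM over the libraries, carry a symbol and have groups that did not overlap. In each list, up to 4 members with the smallest p among those past the test could be named. Genes named outside the rule are identified as such, and some genes under the rule are not reported here.

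Replicates were compared before they were averaged. Over genes with at least 50 counts in a pair, the chi-square per degree of freedom between replicates ran from 4.40 to 16.6, so no pair agreed within sampling noise. The labels give same-numbered replicates of both groups a shared day, which pairs them. The deviations of same-numbered libraries from their group means correlated across genes at 0.055, -0.095 and 0.045. Genes are not independent replicates, so these 3 values describe the libraries only. The main fit had no block, and a fit with the replicate number as a block was an alternative. The exact permutation tests ignored the pairs as well. An exact sign-flip test, which keeps the pairs, cannot go below 0.25.

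The other alternatives were 4 scalings, 2 filters, DESeq2 1.42.0, limma-voom, a stricter threshold of 0.01, and leaving out libraries in turn. Subtraction of background reads was added after seeing the data. Transcript lengths and histone sequence windows for the closing tests came from GENCODE release 29, matched by gene ID and not by coordinates. For histones, matching by symbol was added after a first look, because gene IDs alone gave values for too few of them; intervals from read counts cover counting error only.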

Results

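The series compares A549 cells given siRNA against RPS19 with cells given a non-targeting siRNA, 72 hours after transfection. RPS19 encodes a protein of the small ribosomal subunit. There were 3 libraries per group, with 20814110 to 23889372 counts on genes in each. The comparison asks how the mRNA population of these cells differs after siRNA against a ribosomal protein gene. These libraries do not measure protein.

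RPS19 itself (ENSG00000105372, chromosome 19, 42363988 to 42376994, hg19) fell 35.3-fold. Its level was 1472 ± 96.6 CPM (SD, n = 3) in siOTP and 41.7 ± 4.91 CPM (SD, n = 3) in siRPS19, a log2 fold change of -5.14 ± 0.09 (SE) with adjusted p = 4.98e-12 in edgeR's quasi-likelihood test. The 3 siRPS19 libraries held 1159, 830 and 1073 counts on the gene, and the 3 siOTP libraries 30731, 27124 and 30387. In the authors' deposited table the group RPKM was 348.8 and 12.09.

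**Figure D1:**
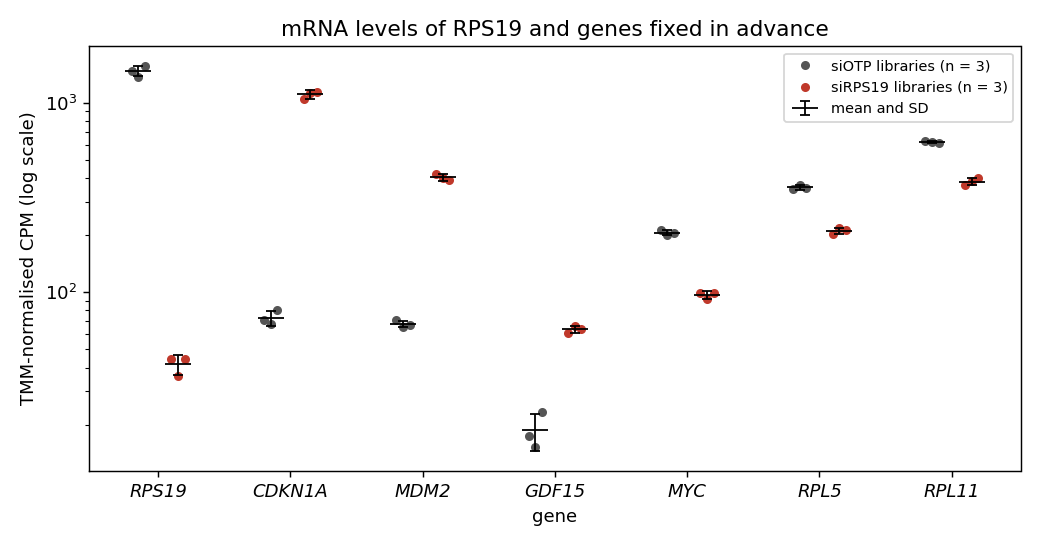
TMM-normalised CPM (log axis) of RPS19 and of 6 genes named whatever their result, with 1 point per library, grey for siOTP and red for siRPS19, and black marks for the mean and SD of 3 libraries. RPS19 fell from 1472 to 41.7 CPM and CDKN1A rose from 73.1 to 1104 CPM.

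Most tested genes differed between the groups. Of 17171 genes, 6778 were higher and 6673 lower after RPS19 siRNA, and 3174 and 2132 of these changed at least 2-fold. The groups did not overlap for 79.7% of the tested genes, where chance gives 10% for 3 against 3. With library totals in place of TMM factors, all genes shifted upward by a median of 0.29 on the log2 scale. That turned the split into 9114 higher and 4734 lower, or 65.8% higher against 50.4%, so directions below are relative to the TMM scale. The libraries also differed in ways apart from single genes. Reads outside genes took 5.81% ± 0.622 of entries in siRPS19 and 3.64% ± 0.232 in siOTP (SD, n = 3 each), and 27933 ± 614 against 25712 ± 227 genes had a count (exact permutation p = 0.1 for both, the smallest possible).

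Genes known to be activated by p53 rose together. Of 52 tested p53 target genes, 50 rose and none fell, over all genes and also adjusted over the list alone, with a median log2 fold change of 1.78 (camera adjusted p = 2.90e-50, and adjusted p = 0.0031 with an estimated correlation). CDKN1A (ENSG00000124762, chromosome 6, 36644305 to 36655116, hg19), the cyclin-dependent kinase inhibitor p21, rose 15.1-fold from 73.1 ± 6.72 to 1104 ± 55.9 CPM (SD, n = 3 each). MDM2 (ENSG00000135679, chromosome 12, 69201956 to 69239214, hg19), which encodes a ubiquitin ligase, rose 5.95-fold from 67.9 ± 2.72 to 404 ± 16.2 CPM (SD, n = 3 each), and overlaps other annotated genes. The antiproliferative gene BTG2 rose 26.9-fold, TP53INP1 27.4-fold, ZMAT3 13.7-fold and the death receptor gene FAS 11.2-fold. GDF15, a secreted stress factor, rose 3.43-fold (log2 fold change 1.78 ± 0.13 SE, adjusted p = 1.26e-05). TP53INP1, FAS and GDF15 overlap other annotated genes as well. The 2 members that did not pass were PLK2, at a log2 fold change of 0.04, and SFN, at 0.01, both named after their values were seen.

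Genes of cell division showed the largest falls. All 52 tested mitosis genes fell, also when adjusted over the list alone, with a median log2 fold change of -5.47 (camera adjusted p = 6.77e-178, and adjusted p = 0.0031 with an estimated correlation). The mitotic cyclin CCNB1 fell 22.7-fold, the spindle midzone gene PRC1 45.6-fold and the checkpoint kinase BUB1 66.9-fold. Of 54 DNA replication genes, 52 fell and 1 rose over all genes and adjusted over the list alone, with a median of -3.24 (camera adjusted p = 2.00e-77, and adjusted p = 0.013 with an estimated correlation). The replicative helicase subunits MCM6 and MCM4 fell 13.7-fold and 10.9-fold, UHRF1 20.1-fold and thymidine kinase TK1 60.7-fold. The exceptions, picked out after their values were seen, were LIG1, which rose by 0.11 on the log2 scale, and CCNE1 at -0.07, which did not pass.

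By the size of the fitted change, the 8 largest falls were DLGAP5 (101-fold), CDC25C (97.5-fold), DTL (87.6-fold), CKAP2L (83.5-fold), DEPDC1 (82.8-fold), UBE2C (79.8-fold), PBK (77.8-fold) and NEK2 (77.5-fold). DLGAP5 fell from 149 ± 0.672 to 1.47 ± 0.110 CPM (SD, n = 3 each). Among the 8 largest rises, CLCA2 had no count in any siOTP library and 24.1 ± 1.89 CPM in siRPS19 (SD, n = 3), which makes it at least 480-fold higher against a floor of 3 counts over the siOTP group. RGMA had 3 counts over the siOTP group and a ratio of 433 (95% counting interval 148 to 2101), and CELF2 had 2 counts and a ratio of 362 (99.8 to 2991). DRAXIN rose 126-fold, the riboflavin transporter gene SLC52A1 117-fold, the tetraspanin gene CD82 89.0-fold, NTN1 84.3-fold and GRIN2C 80.7-fold. RGMA, CELF2, CD82 and NTN1 overlap other annotated genes, as do CDC25C, DTL, CKAP2L, DEPDC1 and PBK, and reads of a partner on the other strand cannot be separated.

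The mRNAs of both ribosomal subunits were lower. For the small subunit, with RPS19 left out, 31 of 32 genes fell, over all genes and adjusted over the list alone, with a median log2 fold change of -0.68. Camera gave adjusted p = 0.00039, and adjusted p = 0.50 with an estimated correlation. For the large subunit, 47 of 48 genes fell on both counts, with a median of -0.75. Camera gave adjusted p = 3.00e-08, and adjusted p = 0.37 with an estimated correlation. RPS13 fell 2.02-fold and RPS3 1.93-fold, and RPL10A 2.95-fold, RPL3 2.84-fold and RPL7A 2.52-fold. RPL5 and RPL11, whose proteins bind MDM2, fell 1.69-fold (from 357 ± 9.82 to 211 ± 7.13 CPM) and 1.62-fold (from 619 ± 6.28 to 383 ± 16.7 CPM; SD, n = 3 each). RPS20, at a log2 fold change of 0.01, was the small-subunit gene that did not pass and is named after its value was seen. With library totals, 25 small-subunit genes fell and 2 rose, and 46 large-subunit genes fell and 1 rose. The mean log2 CPM of the small-subunit genes minus that of the large-subunit genes was -0.22 ± 0.01 in siOTP and -0.09 ± 0.01 in siRPS19 (SD, n = 3 each), a difference of 0.12 (exact two-sided permutation p = 0.1, the smallest possible). Ribosomal protein genes have many processed pseudogenes, and how the counting divided reads between them is not known.

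**Figure D2:**
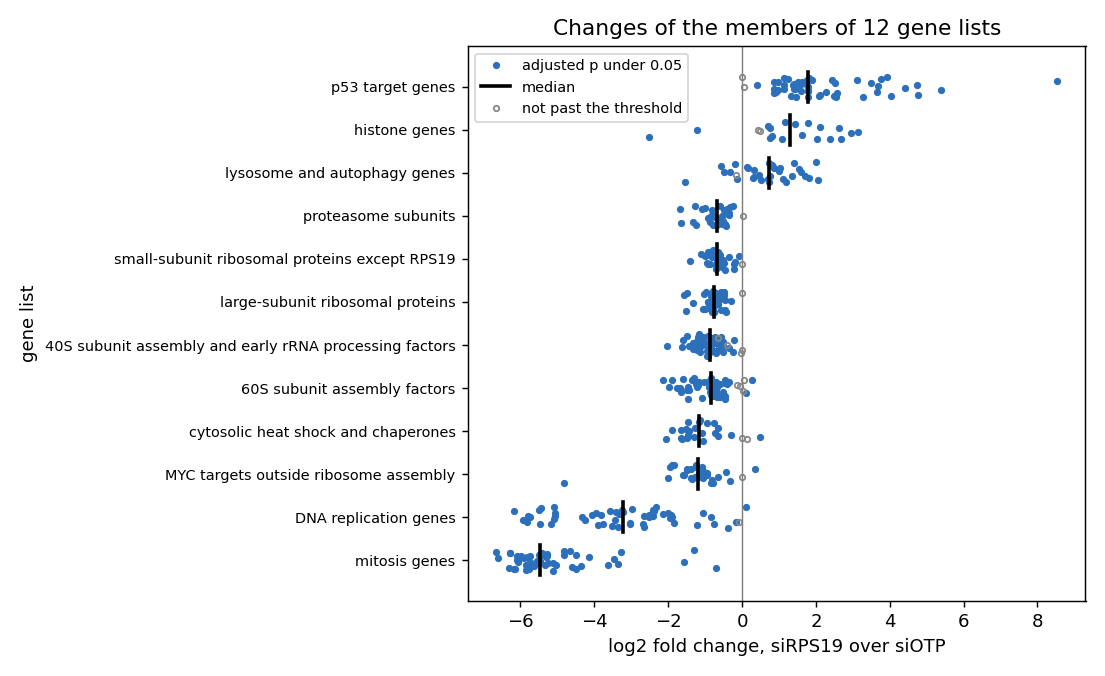
Log2 fold changes (horizontal axis, siRPS19 over siOTP) of the members of selected gene lists, with 1 point per gene, filled where adjusted p was under 0.05 and open otherwise, and a black bar at each median. The medians run from -5.47 for mitosis genes to 1.78 for p53 target genes.

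Genes for building ribosomes were lower as well. Of 53 factors for the 40S subunit and early rRNA processing, 49 fell and none rose over all genes and adjusted over the list alone (camera adjusted p = 1.19e-12, and adjusted p = 0.018 with an estimated correlation). FBL, the methyltransferase of box C/D ribonucleoproteins, fell 4.10-fold, NOLC1 3.08-fold and NOP56 3.04-fold. Of 54 factors for the 60S subunit, 48 fell and 2 rose over all genes, and 49 and 2 adjusted over the list alone (URB1 and EFTUD1 rose, by 0.27 and 0.12 on the log2 scale, named after their values were seen; camera adjusted p = 4.03e-13, and adjusted p = 0.034 with an estimated correlation). With library totals, 46 of the 40S factors fell and 2 rose, and 47 of the 60S factors fell and 5 rose. The nucleolar proteins' genes NPM1 and NCL fell 3.95-fold and 3.15-fold, GTPBP4 3.38-fold and RRP1B 3.72-fold. Of 15 RNA polymerase I genes, 12 fell over all genes and 13 adjusted over the list alone, among them POLR1E (2.89-fold) and UBTF (2.02-fold). Of 17 small nucleolar RNA host genes, 14 fell and 2 rose on both counts, among them SNHG5 (3.20-fold) and GAS5 (2.45-fold) downward, with SNHG14, which overlaps many annotated genes, 2.00-fold higher. Both lists passed camera (adjusted p = 0.0044 and 0.00085) but not with an estimated correlation (adjusted p = 0.13 and 0.21). Of 16 genes with terminal oligopyrimidine mRNAs outside the ribosome, mostly translation factors, 15 fell on both counts. They include the initiation factor genes EIF3E (2.09-fold) and EIF4B (1.93-fold) and HNRNPA1 (3.82-fold), which encodes an RNA-binding protein and not a translation factor. Camera gave adjusted p = 0.00039 for the list, and adjusted p = 0.26 with an estimated correlation.

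MYC fell 2.13-fold, from 206 ± 6.24 to 96.6 ± 4.22 CPM (SD, n = 3 each, adjusted p = 1.81e-15). Of 32 MYC targets outside ribosome assembly, 30 fell and 1 (NME1, by 0.35 on the log2 scale, named after its value was seen) rose on both counts, PAICS falling 3.89-fold and RANBP1 3.98-fold, with camera adjusted p = 1.01e-14 and adjusted p = 0.10 with an estimated correlation. Of 31 proteasome subunit genes, 30 fell on both counts, PSMD11 by 3.16-fold and PSMD7 by 3.21-fold (camera adjusted p = 6.96e-07, and adjusted p = 0.13 with an estimated correlation). Of 25 heat shock and chaperone genes, 22 fell and 1 (DNAJB4, by 0.50 on the log2 scale, named after its value was seen) rose on both counts, HSPD1 falling by 3.76-fold and HSP90AB1 by 3.07-fold (camera adjusted p = 2.64e-09, and adjusted p = 0.26 with an estimated correlation).

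Metabolic lists were mostly lower. Of 73 mitochondrial ribosomal protein genes, 68 fell and 3 rose, and of 70 nuclear oxidative phosphorylation genes, 52 fell and 5 rose, on both counts. Among those that rose were MRPL53, by 0.61 on the log2 scale, and NDUFA13, by 1.81, both named after their values were seen. MRPS27 fell 2.99-fold and ATP5B 2.71-fold. Camera gave adjusted p = 4.03e-06 and 0.0059, and with an estimated correlation adjusted p = 0.26 and 0.59. With library totals, 27 oxidative phosphorylation genes fell and 22 rose. Of 43 targets of the amino acid response factor ATF4, 31 fell and 7 rose over all genes, and 31 and 8 adjusted over the list alone. SLC7A1 fell 10.5-fold and MTHFD2 6.06-fold, while SESN2, which is also a p53 target, rose 12.5-fold (camera adjusted p = 6.30e-09, and adjusted p = 0.13 with an estimated correlation). Of 41 NRF2 targets, 32 fell and 5 rose on both counts, the falls including the glutathione synthesis genes GCLM (2.62-fold) and GCLC (2.85-fold), with camera adjusted p = 0.0037 and adjusted p = 0.59 with an estimated correlation. Of 22 glycolysis genes, 13 fell and 5 rose on both counts, the falls including TPI1 (3.79-fold) and LDHA (3.58-fold). Camera gave adjusted p = 0.028 for glycolysis, and adjusted p = 0.28 with an estimated correlation, 0.066 with library totals and 0.063 with a filter at a mean CPM of 1 (0.00015 to 0.28 over all camera alternatives). With library totals, 10 glycolysis genes fell and 9 rose, with a median of -0.04 against -0.32, and 23 NRF2 targets fell and 9 rose, with a median of -0.15 against -0.43. On that scale 49 mitochondrial ribosomal protein genes fell and 5 rose, and 12 nonsense-mediated decay genes fell and 7 rose. Of 20 targets and factors of nonsense-mediated decay, 13 fell and 2 rose on both counts, with ATF4 3.06-fold lower and SMG6 2.57-fold higher (camera adjusted p = 0.0071, and adjusted p = 0.13 with an estimated correlation).

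Lists that rose included lysosome and autophagy genes, where 26 of 33 rose and 6 fell on both counts (camera adjusted p = 4.77e-06, and adjusted p = 0.048 with an estimated correlation). With library totals, 27 rose and 3 fell. The lysosomal enzyme genes GAA and TPP1 rose 4.01-fold and 2.65-fold and GABARAPL1 3.03-fold, and GLA fell 2.92-fold. Of 20 tested histone genes, 16 rose and 2 fell on both counts, with HIST1H2AC 7.73-fold and HIST1H1C 6.16-fold higher and H1F0 2.34-fold lower (camera adjusted p = 0.0018, and adjusted p = 0.24 with an estimated correlation). Histone genes share sequence, so reads may have been divided between them by the counting, and HIST1H2BK, 4.12-fold higher, overlaps HIST1H4I. Of 40 interferon-stimulated genes, 26 rose and 8 fell on both counts, with TAP1 3.10-fold and STAT2 2.75-fold higher (camera adjusted p = 0.016, and adjusted p = 0.13 with an estimated correlation). Of 35 apoptosis regulators, 17 rose and 13 fell on both counts. The genes for the proapoptotic proteins BBC3 and APAF1 rose 12.9-fold and 3.69-fold, and CYCS, which encodes cytochrome c, fell 6.74-fold. Camera gave adjusted p = 0.023 for apoptosis regulators, and adjusted p = 0.14 with an estimated correlation, 0.058 without a filter and 0.11 with limma-voom (0.012 to 0.14 over all camera alternatives). With library totals, 21 apoptosis regulators rose and 8 fell, and 28 interferon-stimulated genes rose and 5 fell.

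Of the 33 lists tested, 23 passed camera, 5 higher and 18 lower, and with an estimated correlation 2 higher and 4 lower held: p53 targets, lysosome and autophagy, mitosis, DNA replication and both sets of assembly factors. Regroupings of the libraries that mixed both groups also gave up to 23 lists past camera. Each regrouping still holds part of the siRNA difference, so it cannot decide whether the count of lists is particular to the siRNA. The lists that did not pass were those for the unfolded protein response (18 of 27 fell, 6 rose, adjusted p = 0.15), NF-kB inflammatory genes (15 of 25 fell, 7 rose, 0.081), cholesterol synthesis (11 of 25 rose, 7 fell, 0.15), fatty acid synthesis (11 of 15 fell, 3 rose, 0.44), hypoxia (8 of 20 rose, 7 fell, 0.35), TGF-beta and matrix genes (19 of 29 rose, 8 fell, 0.15), epithelial and alveolar genes (6 of 18 rose, 6 fell, 0.23), senescence-associated factors (9 of 23 rose, 10 fell, 0.81) and mitochondrially encoded mRNAs (1 of 13 rose, 0.66). Adjusted over the list alone, these counts moved by at most 1 gene in either direction, and MT-ND3, the 1 mitochondrially encoded gene that rose, no longer passed. The medians of the unfolded protein response, fatty acid synthesis and senescence lists were negative (-0.17, -0.23 and -0.07) and turned positive with library totals (0.12, 0.05 and 0.22), the first and last also with upper-quartile factors (0.00 and 0.11). With library totals, 10 unfolded protein response genes fell and 13 rose, 18 cholesterol synthesis genes rose and 4 fell, and 5 fatty acid synthesis genes fell and 5 rose. On that scale 10 NF-kB genes rose and 13 fell, 12 hypoxia genes rose and 6 fell, 10 epithelial and alveolar genes rose and 5 fell, and 12 senescence-associated genes rose and 9 fell. Without a filter on low counts, camera passed the lists for the unfolded protein response (adjusted p = 0.0016), NF-kB inflammatory genes (0.0023), fatty acid synthesis (0.0065) and TGF-beta and matrix genes (0.045), and with limma-voom that for the unfolded protein response (0.048). Over all camera alternatives the adjusted p ran from 0.0016 to 0.59 for the unfolded protein response and from 0.0065 to 0.76 for fatty acid synthesis. The TGF-beta and matrix list also passed with the replicate block (adjusted p = 0.043), without siRPS19 replicate 3 (0.031) and without replicate 3 of both groups (0.032), in a range of 0.031 to 0.66 over all camera alternatives. The NF-kB list also passed without siOTP replicate 1 (0.048), without siOTP replicate 3 (0.029) and without replicate 3 of both groups (0.039), in a range of 0.0023 to 0.26. Within these lists, SERPINE2 rose 6.72-fold, MMP2 7.00-fold and KRT19 6.85-fold, and CCL2 fell 5.12-fold. In the TGF-beta and matrix list, the other genes eligible by the rule, CYR61, THBS1 and VIM, fell, CYR61 by 2.71-fold, although 19 of its 29 genes rose. In the senescence and epithelial lists, AREG and MUC5AC fell, while IGFBP7, ABCA3 and LAMP3 rose. Of markers of other cell types, 2 of 6 tested fibroblast genes rose (PDGFRA and PDGFRB) and 3 fell (COL3A1, COL1A1 and, named after its value was seen, THY1), with a camera direction upward (adjusted p = 0.98) and a median of -0.13 that became 0.16 with library totals and 0.05 with upper-quartile factors. Further, ITGAM rose among 2 tested blood genes, and ESAM, the 1 endothelial gene tested, fell.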

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

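The test of library depth here was chosen after the result was seen. Reads outside annotated genes, which enter no comparison, were 1.60 times as frequent in siRPS19 as in siOTP. Their share was 6.36%, 5.13% and 5.93% of entries in the siRPS19 libraries and 3.68%, 3.85% and 3.39% in the siOTP libraries, with a 95% exact binomial interval of, for example, 6.35% to 6.37% in siRPS19 replicate 1, which covers counting error only. Reads on olfactory receptor genes, which lung cells are not known to transcribe strongly, were also 1.60 times as frequent, at 12.3 ± 2.15 CPM in siRPS19 and 7.70 ± 0.247 CPM in siOTP without TMM scaling (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). They drew attention because both lie above every control library in data outside the main measurement.

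More genes also had a count after RPS19 siRNA, with 27280 to 28498 genes per library against 25468 to 25916. Library depth does not account for it, since after thinning all libraries to the smallest total the mean difference was 2205 genes and every siRPS19 library stayed above every siOTP library. Background reads as the whole cause are argued against as well. After subtraction of each library's rate per kilobase on olfactory receptor genes, 1759 more genes reached 5 counts in siRPS19, again in every library. This threshold and depth differ from those of the thinned comparison. Without thinning, 19575 to 20588 genes per siRPS19 library and 17935 to 18290 per siOTP library reached 5 counts before subtraction. After it, 19208 to 20064 and 17685 to 18016 did. Reads from genomic DNA may contribute: the rise on olfactory receptor genes was 0.659 times (95% counting interval 0.505 to 0.809) what an even spread of the added reads outside genes would give, only just inside the range of 0.5 to 2 set in advance. Unspliced RNA in introns was not separated from reads between genes, and a change in which genes are transcribed after RPS19 siRNA stays open and untested.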

How the results depend on the processing

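Background subtraction was chosen after seeing the data. RPS19 stayed lower under every alternative run, with log2 fold changes from -5.21 to -4.86. Genes higher ranged from 6068 to 9114 and genes lower from 4734 to 7327, and at least 2-fold higher from 2426 to 4234, all within 1.5 times the main count. Genes at least 2-fold lower numbered 1349 with library totals, against 2132, because that scaling shifts all genes upward by a median of 0.29. Leaving out libraries gave 6259 to 6850 higher, 6210 to 6673 lower, 3150 to 3452 at least 2-fold higher and 2139 to 2242 at least 2-fold lower. The replicate block gave 6783 higher and 6701 lower, 3172 and 2130 at least 2-fold, 21 other lists past the test and the same subunit difference of 0.12 (exact sign-flip p = 0.25, the smallest possible). Among lists and named genes, it changed no other call than that of the TGF-beta and matrix list. With an estimated correlation, the ribosomal protein lists no longer passed (adjusted p = 0.50 for the small and 0.37 for the large subunit), and 5 in place of 20 other lists did (5 to 23 over the camera alternatives). By fry, which tests a list against no change and not against other genes, 28 did. The estimate counts the correlation among members, at 0.51 in both ribosomal lists. Lists with an estimate under the preset 0.01 also no longer passed, among them RNA polymerase I (-0.02) and nonsense-mediated decay (-0.04). Correlation among members therefore does not account for every loss. The p53 list passed throughout (adjusted p up to 0.0031). The subunit difference was 0.117 to 0.124 over its alternatives. Of 2830 values of 149 named genes, 2 no longer passed (MT-ND3, adjusted p = 0.057 and 0.082 without replicate 1 or 2 of both groups) and none reversed.

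The fibroblast list, far from the threshold, changed direction with an adjusted p of 0.994 (DESeq2 size factors), 0.877 (upper quartile), 0.757 (library totals), 0.763 (no filter), 0.928 (DESeq2), 0.816 (limma-voom), 0.807 (replicate block) and 0.119 (fry), and from 0.821 to 0.995 with libraries left out. Camera's direction, which is relative to all other genes, changed for mitochondrially encoded mRNAs with library totals (0.878). Their own median stayed positive, at 0.14 with TMM factors and 0.43 with library totals. Camera's direction also changed for senescence-associated factors without replicate 3 (0.915, and 0.608 to 0.963 with libraries left out). For these the cause was not tested. Limma on log2 RPKM was not run, because the RPKM table gives 1 value per group. Depth limits folds of genes near 0 counts, such as CLCA2.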

Other observations

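The genes and families in this part were chosen after their values were seen. Among relatives of ribosomal proteins, RPL22L1 fell 19.4-fold (log2 fold change -4.28 ± 0.06 SE), against a log2 fold change of -0.58 for RPL22. RPS27L, a known p53 target, rose 1.82-fold while RPS27 fell 1.16-fold. Among E2F transcription factors, the activators E2F1 and E2F2 fell 33.3-fold and 43.5-fold and the repressor E2F8 fell 23.0-fold, but the repressor E2F7, also a known p53 target, rose 2.02-fold. LMNB1, which encodes lamin B1, fell 11.3-fold. All passed the edgeR test.

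Families that share the start of their symbol, with at least 10 tested members, were compared by camera, and 32 of 210 passed, but 0 with an estimated correlation (lowest adjusted p = 0.088). Of 32 collagen (COL) genes, 26 rose and 2 fell (adjusted p = 7.35e-06), with COL4A5 9.18-fold higher, and of 10 ABCA lipid transporter genes 9 rose (adjusted p = 1.58e-05), with ABCA1 7.92-fold higher. Of 20 nucleoporin (NUP) genes, 19 fell and 1 rose (adjusted p = 3.31e-09). With an estimated correlation these gave adjusted p = 0.49, 0.38 and 0.14. Their medians kept their sign with library totals. By annotated type, 361 of 725 lincRNA genes rose and 103 fell, and 439 of 737 processed pseudogenes fell and 72 rose, in libraries that also differed in reads outside genes. How the counting divided reads between processed pseudogenes and their parent genes is not known. Counts on pseudogenes may therefore hold reads of the parents, and a fall of pseudogene transcripts is not shown.

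Tests of scaling and of transcript tails below were chosen after the result was seen, as was matching histones by symbol. Ribosomal protein mRNAs were lower, with a median log2 fold change of -0.72 over 80 genes. The choice of TMM over library totals does not explain all of it, since with totals the median was -0.43 (95% bootstrap interval -0.47 to -0.38). Transcript length does not either, since removing its trend left -0.73. Both scalings are relative, so an absolute fall is not shown. Bootstrap intervals here and for histones below resample genes, which are not independent. They do not cover the spread between libraries. Removing the trend on abundance in siOTP left -0.13 (-0.16 to -0.04). A fall shared with other abundant mRNAs may therefore account for most of the change, and a response specific to ribosomal proteins is not shown. The level in siOTP is also the base of the fold change, so the trend is not independent of it. No other list was tested for this trend, so other lists that fell may share it.

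Histone genes were higher, with a median of 1.31 over 20 genes. Reads shared between histone genes are argued against, because 14 genes with at least 80% of their 50-base windows in no other gene had a median of 1.53 (95% bootstrap interval 0.92 to 2.37). Background reads at the rate on olfactory receptor genes were few, at 0.196 to 0.422 per kilobase over the libraries. Their subtraction left a median of 1.30. So few reads could hardly move genes that had passed the count filter, so the subtraction itself decides little. Whether annotated longer transcripts, which may carry a poly(A) tail, rose more cannot be told apart: 12 genes with transcripts over 700 bases exceeded 8 others by 0.31 on average (-0.88 to 1.67), an interval too wide to decide.

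The 10 splits of the libraries are too few for a share under 0.05. The real split, the 1 split that reached its own counts, gave 6778 higher and 6673 lower, and the highest other split gave 0 of either in edgeR's test, also at 2-fold (3174 and 2132 against 0), with 21 to 84 genes at an unadjusted p under 0.05. The 4 splits that part all pairs include the real one, and the others gave 0 genes and up to 23 lists. For gene lists, 4 of the 10 splits, the real one included, gave 23, and the highest other gave 23. Each other split sets 2 libraries of one group with 1 of the other against the reverse, so part of the siRNA difference remains in it. The mix also widens the spread within each set, so few or 0 calls could be foreseen there. The other splits therefore do not measure what chance would give, for genes or for lists.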
